A study of Homo sapiens with 6 samples.

How the data were processed

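RNA was sequenced from 6 samples of ACHN cells, 3 treated with SMALS-329 and 3 with DMSO. The compound's name is spelled in more than one way in the labels, which were read as 1 compound. Per the submitters' processing notes, kallisto and DESeq2 were used with the human build hg38. Their versions, the annotation release and the step from transcripts to genes are not given in the sources used here.

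The series had 1 table, with a row per gene and 6 columns of values. A column was to be used only where its heading matched the labels of a sample or a group. The headings were searched for in all label text of the 6 samples, and 0 of the 6 matched. The 6 columns of values were therefore left out of every result. The file carries LKB1 in its name, and nothing in it ties its columns to the samples of this series. The values were inspected once for their type, range, totals and correlation between columns, to learn what the file holds, and none was normalised, tested or carried into a result. The depth per sample is not reported.

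The results reported here rest on the headings, the gene identifiers and the symbols of the table, which were read with Python 3.11.15. Identifiers were matched without their version suffix to the primary-assembly annotation of GENCODE release 29 on GRCh38. That is the same build that the processing notes name. Both identifier columns held the same identifier in all 40213 rows, and each identifier occurred once.

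Before the data were examined, 34 gene lists holding 876 distinct gene names were written down, together with a rule for the genes to be named. The lists were chosen to fit a table with LKB1 in its name, a renal carcinoma line and a small molecule. No known action of SMALS-329 entered that choice. The naming rule took the genes with the largest changes, the leading members of changed lists, and STK11, PRKAA1 and PRKAA2 in every case. Only its last part needs no expression values, so those are the 3 genes located in the report. List members were found by their own symbol in the table. Failing that, they were found by the identifier that a table of current symbols gives, which accounted for 44 of the 875 names found. The lists for which coverage is described in the report were chosen after coverage was seen.

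The comparison fixed in advance was a genome-wide test of SMALS-329 against DMSO with gene list tests. It was not run. Neither were the other settings fixed with it. They concerned the normalization, the filter on low values, the test, the gene list tests and the threshold. They also concerned the spread between libraries, the replicate number as a block, and leaving out each library in turn.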

Results

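Gene expression was measured by RNA sequencing in ACHN cells, an established human renal carcinoma line. The labels describe 6 samples, all collected at 24 hours. In 3 samples the cells had received SMALS-329 at 8 uM, a small molecule known here only by its code name, and in the other 3 they had received the vehicle DMSO. The design implies 1 comparison, SMALS-329 against DMSO, which asks how exposure to the compound changed gene expression in these cells. Replicates were numbered 1 to 3 in each group, and the labels do not say whether they came from separate cultures.

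The comparison was not made, and no expression value, fold change or depth is reported for any gene or sample. The single table of the series had 6 columns of values, whose headings are plain serial names that occur in none of the sample labels. None of the 6 columns could therefore be assigned to a sample, or to the SMALS-329 or the DMSO group. Neither the order of the columns nor the values in them was used in place of a label. Whether SMALS-329 changed the expression of any gene in ACHN cells remained untested here.

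The gene content of the table did not depend on that assignment. The table listed 40213 Ensembl gene identifiers, each with a symbol. Of these, 35512 occurred in GENCODE release 29 on GRCh38, among them 19909 protein-coding genes and 10175 processed pseudogenes. Long non-coding RNA classes were nearly absent from the matched identifiers, with 11 identifiers typed as lincRNA, 3 as antisense and 3 as processed transcript. No matched identifier was typed as a microRNA, small nuclear RNA, small nucleolar RNA or rRNA, other than rRNA pseudogenes. These types describe which genes have a row in the table, not which RNAs were present in the cells. The other 4701 identifiers were not in that release's annotation of the primary assembly. Its annotation of other sequences, such as alternate haplotypes and patches, was not searched. A total of 1821 symbols stood on more than 1 identifier and together covered 5600 identifiers.

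Of the 876 gene names fixed in advance for the comparison, 875 were found in the table. With 19909 protein-coding identifiers matched, near-complete coverage of lists of known genes was close to given and is no finding about them. Being listed means only that the table has a row for the gene, not that its RNA was detected in ACHN cells. STK11, which encodes the kinase LKB1, was listed as ENSG00000118046 and lies on chromosome 19 from 1177558 to 1228435 on the plus strand. PRKAA1 and PRKAA2 encode the catalytic subunits of AMPK, a kinase that LKB1 activates. PRKAA1 (ENSG00000132356) lies on chromosome 5 from 40759379 to 40798374 on the minus strand. PRKAA2 (ENSG00000162409) lies on chromosome 1 from 56645322 to 56715335 on the plus strand. These coordinates are those of GENCODE release 29 on GRCh38, in which all 3 are protein-coding genes. The 3 genes were fixed in advance for a table with LKB1 in its name, and no link from them to SMALS-329 was tested.

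All 35 members of the list of LKB1 and AMPK pathway components were listed, as were all 25 of the list of cholesterol synthesis and uptake. All 13 members of the list of mitochondrially encoded transcripts were listed too. That list does not hold every such transcript, and no matched identifier was typed as a mitochondrial rRNA or tRNA. Of the 24 target genes of CREB and its CRTC coactivators, 23 were listed. The 1 name not found was LINC00473, a long non-coding RNA, a class with few matched identifiers in the table. Why that name was not found was not tested. The 20 aminoacyl-tRNA synthetases were all listed, 18 of them under an older symbol, and the 24 replication-dependent histone genes were all listed under older symbols. Of the 38 names in the list of interferon-stimulated genes, 11 had a symbol that stood on more than 1 identifier. Over the whole table, 1821 of 36434 distinct symbols did. No other list had more than 4 such members, and this list was singled out after coverage was seen.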

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

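No comparison was made, so there was no result of one to repeat under other settings: none of the 6 columns of values was assigned to a sample or group. The settings fixed before the data were examined were not run. They were other scaling factors, other filters on low values, other tests, other gene list tests, a stricter threshold, other settings for the spread between libraries, the replicate block and the omission of each library in turn. No paired analysis was possible because the columns carry no replicate numbers and no group.

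The count of list names found and the count of identifiers found in GENCODE were repeated under settings chosen after seeing the data. With list members matched by symbol alone, 831 of the 876 names were found, against 875 with identifiers as well. The difference is the 44 names found by identifier, so it follows from the matching rule. With the basic annotation of GENCODE release 29, 35477 identifiers were found, against 35512 with the comprehensive one of the primary assembly. These annotations may also differ in the sequences they cover, so the gap cannot be put down to the basic set alone. Neither count bears on how a comparison of the groups would depend on the processing.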
